A study of Mus musculus with 10 samples.

How the data were processed

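RNA was measured in 10 orthotopic mammary tumours grown from MCa-M3C, a mouse mammary tumour cell line, in FVB/N mice. Per the labels, tumours of about 100 mm^3 were assigned to daily intravenous PBS (control, n = 5) or to TMA-ARB at a valsartan dose of 40 mg/kg (n = 5) for 6 days. Poly-A RNA was selected and made into strand-marking libraries with NEBNext kits, per the labels' protocols. The groups were taken from the sample titles. Replicate numbers ran from 1 to 10 with none shared between groups, so no pairing was used.

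The authors deposited a table of estimated counts for 37882 Ensembl genes, with a column per tumour. Per the submitters' processing notes, Salmon and the mm10 build were used; the Salmon version, the transcript annotation, the strand setting and the step that made the estimates whole were not given in the sources used here. All values in the 10 columns were already whole numbers (0 values were not whole), so rounding changed none of them. Every column was matched to a sample by the sample name in the labels, and 0 columns were left unmatched. The library totals ran from 12742953 to 16884621 counts. Salmon divides reads among similar transcripts, so genes with near-identical copies carry extra uncertainty. Reads carried no molecular identifiers in the sources used here, so intervals and floors cover counting error only.

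The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter for the 2 groups, robust dispersion estimates and Benjamini-Hochberg adjustment at 0.05. The filter left 14063 genes. Values are CPM with the TMM-scaled library size, computed here from the deposited counts, and fold changes are TMA-ARB over control. The standard error of a log2 fold change was its absolute value divided by the square root of F. Mean log2 CPM values used a prior count of 2.

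Before the data were examined, 38 gene lists, the tests, other settings to try and the rule for named genes were fixed. Lists with 3 or more measured members (36 of 38) were tested with camera from limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01. The milk and luminal secretory list and the epidermis list had 1 and 2 measured members and were not tested. Camera with an estimated correlation and fry were run beside it. The rule named, in each direction, the 12 called genes of largest fold change with a mean of at least 1 CPM. Where fewer were called it took those and the genes of smallest unadjusted p up to 6, given as not passing. It also named genes of the renin-angiotensin system, among them Agtr1a, Agtr1b, Agtr2, Agt and Ace, the 4 members of smallest p of each called list, and up to 3 called members of any other list. Library totals and shares were compared with a two-sided exact permutation test of the difference in means, over 252 arrangements, whose smallest possible p is 0.00794. Correlations across libraries used 100000 permutations. Correlations with each group's mean removed, added after the data had been seen, permuted the mitochondrial share within groups over all 14400 arrangements.

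The settings fixed then were DESeq2 1.42.0, limma-voom with sample weights, RLE scaling, no low-count filter, a mean of at least 5 CPM, covariates for adipocyte and muscle markers, an adjusted p under 0.10, and leaving out each library in turn. After the data had been seen, settings were added for the mitochondrial share: a log2 covariate, a term for libraries above 5%, the mitochondrial genes left out, the libraries on each side of 5% alone, and the 3 TMA-ARB libraries above 10% left out. An exact permutation test of list means was also added then. DESeq2 gave no adjusted p for 13985 genes, and these stayed without a call. Limma-voom fits means of log2 values, unlike edgeR, so a gap between their fold changes need not come from the weights. The weights ran from 0.352 (TMA-ARB replicate 7) to 2.53 (control replicate 5).

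The edgeR step was tested on simulated counts for this comparison, with 50 genes changed at each fold among 13762 tested. It recovered 2% of genes changed 1.5-fold, 26% at 2-fold, 66% at 3-fold and 74% at 4-fold, with 3 false calls. With no gene changed, 0 of 13753 genes were called and 599 had an unadjusted p under 0.05. Coordinates come from GENCODE mouse release 21 on the same assembly as mm10, matched by Ensembl identifier for 37607 of the 37882 genes. Sequence matches used BLAST+ 2.17.0, and figures used Python 3.11.15 with matplotlib 3.10.9.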

Results

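The series compared the transcriptomes of MCa-M3C mammary tumours in mice given TMA-ARB or PBS. TMA-ARB is an angiotensin receptor blocker, here in a valsartan form, that is built to act in the tumour microenvironment. Valsartan blocks the angiotensin II receptor encoded in mice by Agtr1a and Agtr1b. Each group held 5 tumours, treated daily for 6 days from a volume of about 100 mm^3. The labels name mice bearing tumours but do not state that each library is a separate animal, so p-values measure the spread between these libraries. Library totals averaged 15151100 ± 1050390 counts in controls and 14356900 ± 1133670 under TMA-ARB (SD, n = 5 each; exact permutation p = 0.317). No pair of libraries held identical values, and their log2 counts correlated across genes between 0.947 and 0.979; genes are not independent replicates.

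The question was which genes and gene groups differ between treated and control tumours. Lymphocyte, antigen presentation, interferon, endothelial and immediate early gene lists lay lower under TMA-ARB, and cell cycle, cholesterol synthesis, epithelial and mitochondrially encoded lists lay higher, in a set test with a preset correlation. The median member of the cytotoxic lymphocyte list had a log2 fold change of -1.09 and that of the T cell list -0.69. These list calls did not hold with other set tests: 0 of 36 lists passed camera with an estimated correlation (5 at unadjusted p under 0.05), 0 passed fry (4) and 0 passed the exact permutation test of list means (4). The exact permutation test adds little here. Its smallest possible p is 0.00794, so 1 list alone could not pass after adjustment over 36 lists. The smallest unadjusted p it gave was 0.0317. No single gene passed. EdgeR called 0 of 14063 genes at an adjusted p under 0.05, with 457 at an unadjusted p under 0.05 (224 higher, 233 lower). Uniform p-values would give 703, but other splits of the same libraries, 5 against 5, gave from 64 to 2889. The gap between 457 and 703 therefore carries no meaning.

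DESeq2 called 1 gene higher and 1 lower. The higher gene was Amd2, a copy of the gene for S-adenosylmethionine decarboxylase, with a log2 fold change of 1.47 ± 0.29 (SE; DESeq2 adjusted p = 0.0106). The lower gene was Hist1h2br, a histone gene, at -4.04 ± 0.86 (adjusted p = 0.0327) and a mean of 0.899 CPM. Hist1h2br falls outside the named-gene rule and was named after its values were seen. Both have near-identical relatives whose reads the counting can divide, and neither passed edgeR (adjusted p = 0.997 for both). Limma-voom with sample weights called 0 genes, with 1389 at an unadjusted p under 0.05.

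The 6 genes of smallest unadjusted p in each direction, among those with a mean of at least 1 CPM, did not pass edgeR. In the higher direction, Amd2 (chromosome 10, 35708675 to 35711892) measured 10.9 ± 2.66 CPM in controls and 30.1 ± 12.4 under TMA-ARB (SD, n = 5). Msx1, a homeobox gene on chromosome 5 (37820485 to 37824583), measured 0.762 ± 0.388 and 2.89 ± 1.09 CPM. Mir17hg, the host gene of a microRNA cluster, had a log2 fold change of 1.29 ± 0.37 (SE). Ucn2, which encodes a urocortin peptide, had 1.41 ± 0.43, Zfp948 0.85 ± 0.27 and Ndufb4 1.40 ± 0.43. In the lower direction, Adamts1, a matrix protease gene on chromosome 16 (85793827 to 85803113), measured 70.8 ± 21.8 CPM in controls and 36.5 ± 5.19 under TMA-ARB. Trib2 (chromosome 12, 15791727 to 15816922) measured 29.0 ± 4.35 and 14.9 ± 3.73 CPM, and Bcl2l11, which encodes the pro-apoptotic protein Bim, 39.7 ± 4.22 and 21.6 ± 6.66 CPM. Zfp358 had a log2 fold change of -0.93 ± 0.21. Npr3, a natriuretic peptide clearance receptor gene, had -1.61 ± 0.41, and Irf8, a transcription factor of myeloid and B cells, -0.74 ± 0.19. All 5 TMA-ARB libraries lay on the same side of the control mean for each of these genes except Zfp948 and Ndufb4 (4 of 5), and the adjusted p was 0.997 for all 12. With 1 library left out, all 6 higher genes came nearest to 0 without TMA-ARB replicate 9: Amd2 1.18, Msx1 1.66, Mir17hg 1.03, Ucn2 1.19, Zfp948 0.72 and Ndufb4 0.99. Without control replicate 2 Npr3 was at -1.15 and Adamts1 at -0.76. The nearest for Trib2 was -0.83, Zfp358 -0.79, Bcl2l11 -0.76 and Irf8 -0.61.

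**Figure D1:**
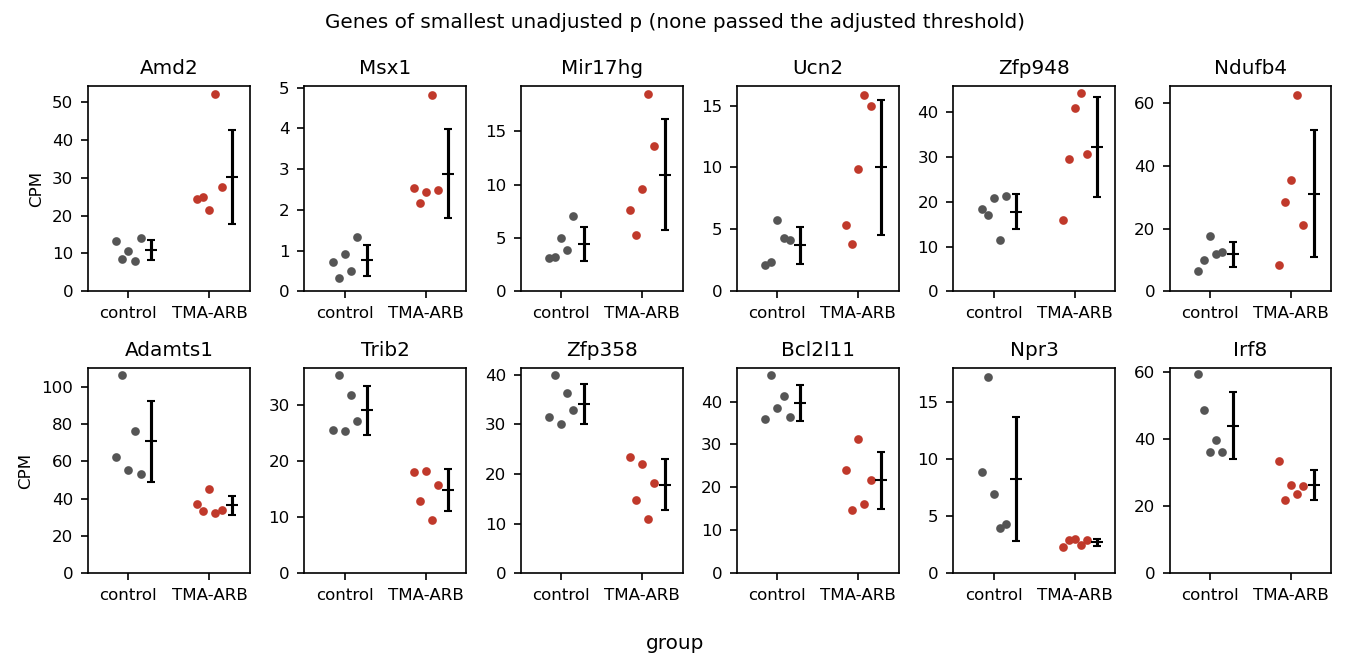
CPM of the 6 genes of smallest unadjusted p in each direction, among those with a mean of at least 1 CPM, in each library of the control (grey) and TMA-ARB (red) groups, with a separate linear axis per gene; black marks give the mean and SD of 5 libraries. Amd2 averaged 10.9 CPM in controls and 30.1 under TMA-ARB, and Adamts1 70.8 and 36.5, and no gene shown passed the adjusted threshold in edgeR.

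The libraries differed in the share of counts from mitochondrially encoded genes. It was 4.19% ± 2.21 in controls and 10.5% ± 9.12 under TMA-ARB (SD, n = 5), a difference of 6.31 points (exact permutation p = 0.143). It ran from 2.07% (95% exact binomial interval 2.07 to 2.08) in control replicate 2 to 25.0% (24.9 to 25.0) in TMA-ARB replicate 9. Without TMA-ARB replicate 9 the difference was 2.69 points, and without TMA-ARB replicate 6 it was 8.38 points with an exact permutation p of 0.0397. The 5% line parted the libraries as the sign of the first principal component did, which held 39.7% of the variance: control replicates 3 and 4 and TMA-ARB replicates 8, 9 and 10 lay above it. Those controls were at 6.37% and 6.63% and those TMA-ARB libraries at 10.5%, 25.0% and 11.7%. Values given for libraries above the line therefore do not hold the share fixed, for any list. The 13 mitochondrially encoded genes had a median log2 fold change of 1.66 and all 13 were positive. That median was 0.93 without TMA-ARB replicate 9. It was 0.12 in libraries below the 5% share and 1.61 above it, and without TMA-ARB replicates 8, 9 and 10 it was -0.60 and the list was called lower. With the log2 mitochondrial share as a covariate it was 0.071 and the call ended (adjusted p = 0.160). That share is computed from the counts of these same genes, so the outcome was fixed by construction and tests nothing about the list. For mt-Nd3 (base 9459 to 9806 of the mitochondrial genome) the means were 129 ± 68.3 and 406 ± 340 CPM, and for mt-Nd4 1772 ± 924 and 6318 ± 6252 CPM. The list was called higher (camera adjusted p = 7.6e-09), but not with an estimated correlation: adjusted p = 0.313 with an estimated correlation. Of its members 0 passed over all genes and 0 adjusted over the list alone, with 9 at an unadjusted p under 0.05.

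**Figure D2:**
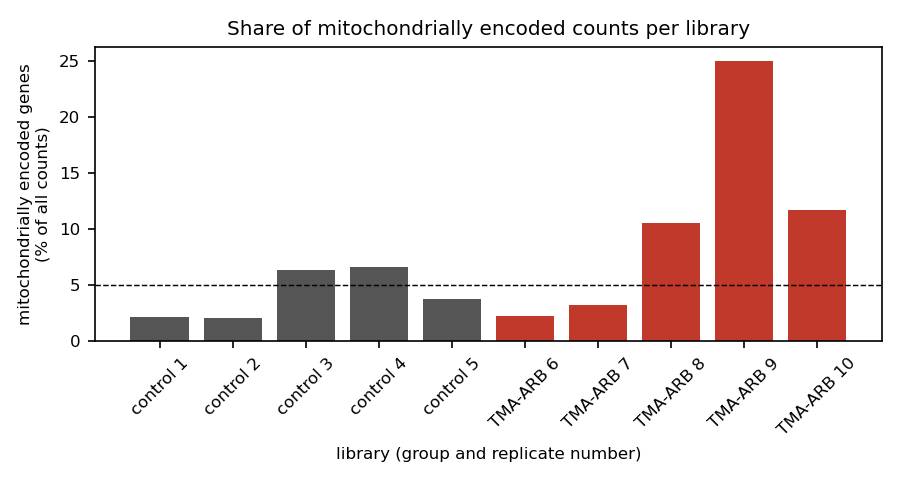
Percent of each library's counts from mitochondrially encoded genes, by group and replicate, with controls in grey, TMA-ARB in red and the 5% line dashed. Replicate 9 of TMA-ARB reached 25.0%, and controls lay between 2.07% and 6.63%.

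Ace, which encodes angiotensin-converting enzyme (chromosome 11, 105967945 to 105989964), measured 42.5 ± 32.2 CPM in controls and 16.5 ± 9.78 under TMA-ARB, a log2 fold change of -1.36 ± 0.50 that did not pass (edgeR adjusted p = 0.997). Agt, the angiotensinogen gene, measured 3.09 ± 2.67 and 1.53 ± 0.70 CPM. Mme, which encodes neprilysin, measured 678 ± 280 and 438 ± 181 CPM (log2 fold change -0.63), and Agtrap had a log2 fold change of -0.28. With 1 library left out the values came as near to 0 as Ace -0.78 without control replicate 2, Agt -0.45 without control replicate 2 and Agtrap -0.16 without TMA-ARB replicate 10. Agtr1a held 72 counts over 7 libraries and Agtr1b 7 counts, all in TMA-ARB replicate 9; both were too low to test. Agtr2 had 0 counts in every library, which allows up to 3 counts, or 0.178 to 0.235 CPM per library. Of the 7 measured members of the list 6 were negative, with a median of -0.28 (-0.32 in libraries below a 5% mitochondrial share and -0.18 above). The list was called lower (camera adjusted p = 0.0185; adjusted p = 0.313 with an estimated correlation). The call was lost without control replicate 2 or TMA-ARB replicate 10 (adjusted p 0.0572 to 0.0995), and with the log2 mitochondrial share as a covariate (median -0.21, adjusted p = 0.0588). No member passed over all genes (0) or adjusted over the list alone (0), with 1 at an unadjusted p under 0.05.

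Matrix and fibroblast lists had small negative medians with members on both sides of 0. Of 18 collagens 14 were negative (median -0.28, camera adjusted p = 0.00894; adjusted p = 0.486 with an estimated correlation). Col6a1 had a log2 fold change of -0.62 ± 0.24 and Col6a2 -0.84 ± 0.35, while Col1a2 had 0.59 ± 0.28 and Col8a1 0.52 ± 0.19. Of 27 crosslinking and remodelling genes 19 were negative (median -0.27, camera adjusted p = 0.000573; adjusted p = 0.313 with an estimated correlation), among them Mmp14 at -0.56 and Tgm2, a transglutaminase gene, at -0.49. Myofibroblast and mural markers had a median of -0.23 with 13 of 16 negative (camera adjusted p = 0.0333; adjusted p = 0.344 with an estimated correlation). Pdgfrb was at -0.58 and Des at -2.83 ± 1.16 (30.6 CPM in control replicate 1 and at most 8.37 in the other controls; with sample weights -0.60), and Tagln, a smooth muscle gene, was at 1.06 ± 0.64 (-0.13 with sample weights). With 1 library left out the nearest values to 0 were Col6a1 -0.40 without control replicate 2, Col6a2 -0.53 without control replicate 2, Des -1.25 without control replicate 1 and Tagln 0.53 without TMA-ARB replicate 6. Among libraries below a 5% mitochondrial share the myofibroblast median was 0.51, and above it was -0.77, so the direction differed between the sides. The collagen medians were -0.12 and -0.45 there, and the crosslinking medians -0.33 and 0.03. The TGF-beta list had 17 of 19 members negative (median -0.15, camera adjusted p = 0.000924; adjusted p = 0.313 with an estimated correlation), with Tgfb3 at -0.75 ± 0.22 and Tgfb1 at -0.72 ± 0.28, and medians of -0.18 below the 5% share and -0.22 above it. In these lists 0 members passed over all genes and 0 adjusted over the list alone. Unadjusted p under 0.05 was reached by 3 collagens, 2 crosslinking genes, 2 myofibroblast genes and 3 TGF-beta genes. With 1 library left out, the collagen median was -0.44 without control replicate 1, -0.14 without control replicate 2 and -0.47 without TMA-ARB replicate 6. The crosslinking median was -0.030 without control replicate 2, -0.42 without TMA-ARB replicate 8 and -0.14 without TMA-ARB replicate 9, and the TGF-beta median -0.088 without control replicate 2 and -0.23 without TMA-ARB replicate 8. The myofibroblast median was -0.078 without control replicate 3, -0.033 without control replicate 4, -0.42 without TMA-ARB replicate 6, -0.085 without TMA-ARB replicate 8, -0.11 without TMA-ARB replicate 9 and -0.10 without TMA-ARB replicate 10. With the log2 mitochondrial share as a covariate the collagen and myofibroblast calls ended (medians -0.19 and -0.16, adjusted p 0.771 and 0.630), while the crosslinking and TGF-beta lists were still called lower (-0.27 and -0.16). The collagen call was lost without control replicate 2 or TMA-ARB replicate 9 (adjusted p 0.0871 to 0.154). The myofibroblast call was lost without control replicate 2 or 3 or TMA-ARB replicate 8 or 10 (0.108 to 0.226).

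Endothelial markers were negative in 17 of 20 cases, with a median of -0.38 (camera adjusted p = 1.3e-05; adjusted p = 0.313 with an estimated correlation). Flt1, a VEGF receptor gene, measured 75.9 ± 13.9 CPM in controls and 51.7 ± 15.3 under TMA-ARB, and Plvap, a gene of endothelial diaphragms, had a log2 fold change of -0.51 ± 0.21 (SE). Angpt2 and Apln had log2 fold changes of -1.01 and -0.60 (Angpt2 -0.47 without control replicate 2 and Apln -0.37 without control replicate 2). The endothelial median was -0.13 among libraries below a 5% mitochondrial share and -0.38 among those above; with the log2 share as a covariate it was -0.20 and the list was still called lower. The hypoxia list had a median of -0.25 with 15 of 19 negative (camera adjusted p = 0.000798; adjusted p = 0.497 with an estimated correlation), with Pfkfb3 at -0.72 and Ldha at -0.39 (Pfkfb3 -0.18 without control replicate 2 and Ldha -0.18 without control replicate 2). Below the 5% share its median was -1.51 and above it was 0.55, so the direction differed between the sides of the split; with the log2 share as a covariate it was -0.67 and still called lower. Without control replicate 2 the hypoxia median was 0.05 and the call was lost, as it was without TMA-ARB replicate 6 (adjusted p 0.0712 to 0.518). The other hypoxia medians that moved were -0.025 without TMA-ARB replicate 6, -0.075 without TMA-ARB replicate 7, -0.57 without TMA-ARB replicate 8 and -0.16 without TMA-ARB replicate 9. Passing members numbered 0 over all genes and 0 adjusted over the list alone in both lists, with 4 endothelial and 0 hypoxia members at an unadjusted p under 0.05. Ldha and Eno1 have processed pseudogenes that can share reads.

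All 13 cytotoxic lymphocyte genes were negative (median -1.09, camera adjusted p = 6.8e-06; adjusted p = 0.313 with an estimated correlation). Nkg7 measured 7.14 ± 1.47 CPM in controls and 3.50 ± 0.952 under TMA-ARB. Prf1, which encodes perforin, measured 40.1 ± 47.7 and 5.62 ± 2.81 CPM, and Gzmb, a granzyme gene, 24.4 ± 22.8 and 8.47 ± 3.65. Control replicates 1 and 2 carried both differences: Prf1 was at 88.6 and 95.9 CPM there and at 3.88 to 7.61 in the other controls, and Gzmb at 39.2 and 57.2. With sample weights their log2 fold changes were -1.28 and -0.51, against -2.82 and -1.52 in edgeR. Control replicates 1 and 2 had weights of 1.05 and 0.831, so the gap need not come from the weights. All 19 T cell markers were negative (median -0.69, camera adjusted p = 0.000281; adjusted p = 0.313 with an estimated correlation), with Il2rb at -1.28 and Cd3g at -0.79. Checkpoint and regulatory T cell genes had a median of -0.52 with 13 of 16 negative (camera adjusted p = 0.000924; adjusted p = 0.313 with an estimated correlation), with Havcr2 at -0.82 ± 0.24, Icos at -1.23 and Ctla4 at -1.52. Ctla4 was at 6.90 and 9.71 CPM in control replicates 1 and 2 and at most 2.55 in the other controls. With sample weights Icos was at -0.30, Ctla4 at -0.15 and Il2rb at -0.74, and without control replicate 2 Gzmb was at -0.93 and Ctla4 at -0.89. Below a 5% mitochondrial share the cytotoxic, T cell and checkpoint medians were -1.22, -0.48 and -0.59, and above it -0.37, -0.33 and -0.43. With the log2 mitochondrial share as a covariate they were -0.66, -0.51 and -0.50, and all 3 lists were still called lower. Control replicates 1 and 2 also held the highest list means: against the control mean they were at 0.95 and 0.75 for cytotoxic genes (other controls -0.78 to -0.28, TMA-ARB -1.32 to -0.56). For checkpoint genes they were at 0.58 and 0.48 (other controls -0.44 to -0.19, TMA-ARB -0.82 to -0.31), and for T cell markers at 0.54 and 0.16 (-0.35 to -0.08, and -0.91 to 0.06). The counts of members passing were 0 over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 7 cytotoxic, 1 T cell and 2 checkpoint members.

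The 10 genes of MHC class II presentation were all negative, with a median of -0.74 (camera adjusted p = 1.2e-05; adjusted p = 0.313 with an estimated correlation). Cd74, the invariant chain gene, measured 618 ± 246 CPM in controls and 319 ± 173 under TMA-ARB, and H2-Aa 181 ± 69.9 and 97.2 ± 51.3. Control replicates 1 and 2 held class II list means of 0.62 and 0.57 against the control mean (other controls -1.02 to -0.01, TMA-ARB -1.46 to 0.10). Class I genes had a median of -0.16 with 11 of 13 negative (camera adjusted p = 0.00546; adjusted p = 0.381 with an estimated correlation), a call lost without TMA-ARB replicate 7 (adjusted p 0.255). The class I median was -0.25 without control replicate 2, -0.10 without control replicate 4 and -0.088 without TMA-ARB replicate 7. Tap1 was at -0.41; H2-D1, at -0.31, belongs to a family of similar genes. Interferon response genes were negative in 26 of 30 cases (median -0.34, camera adjusted p = 7.6e-08; adjusted p = 0.313 with an estimated correlation), with Isg15 at 74.3 ± 23.1 CPM in controls and 44.8 ± 7.51 under TMA-ARB and Bst2 at 114 ± 9.31 and 85.2 ± 13.4. The interferon median was -0.14 without TMA-ARB replicate 7. Below a 5% mitochondrial share the class II, class I and interferon medians were -0.80, -0.30 and -0.67, and above it -0.50, -0.21 and -0.10. With the log2 share as a covariate they were -0.48, -0.30 and -0.33, and all 3 lists were still called lower. Unadjusted p under 0.05 was reached by 2 class II, 0 class I and 3 interferon genes, with 0 passing over all genes and 0 adjusted over the list alone.

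Macrophage and monocyte markers had a median of -0.40 with 18 of 22 negative (camera adjusted p = 1.2e-05; adjusted p = 0.347 with an estimated correlation). Apoe measured 1404 ± 277 CPM in controls and 851 ± 234 under TMA-ARB, and Aif1 58.1 ± 11.8 and 41.1 ± 9.65. Across the 10 libraries the list mean fell with the log2 mitochondrial share (Pearson r = -0.97, permutation p = 3e-05, adjusted p = 0.00105 over 35 lists; Spearman rho = -0.96, p = 3e-05, adjusted p = 0.00105). Without the 2 libraries farthest from the median share r was -0.95. With each group's mean removed it was -0.97 (exact permutation within groups p = 0.000764, adjusted p = 0.0267). The macrophage median was -0.25 without control replicate 1, -0.24 without control replicate 2 and -0.22 without TMA-ARB replicate 9. It was 0.04 below the 5% share and -0.67 above it. With the log2 share as a covariate it was -0.12 and the call ended (adjusted p = 0.888). Mast cell markers had a median of -0.53 with 6 of 7 negative (camera adjusted p = 0.0185; adjusted p = 0.442 with an estimated correlation), with Hdc at -0.99 and Kit at -0.56 (Hdc -0.62 without control replicate 1 and Kit -0.24 without control replicate 2). Their mean fell with the mitochondrial share too (r = -0.90, permutation p = 0.00034, adjusted p = 0.00595; rho = -0.92, p = 0.00062, adjusted p = 0.0108; r = -0.94 without the 2 libraries). With each group's mean removed r was -0.89 and missed the threshold (exact permutation within groups p = 0.00493, adjusted p = 0.0863). Their median was -0.10 below the 5% share and -1.03 above it. With 1 library left out the mast cell median was 0.0046 without control replicate 1, -1.36 without TMA-ARB replicate 6, -0.28 without TMA-ARB replicate 8 and -0.35 without TMA-ARB replicate 10. The covariate ended the mast cell call too (median -0.056, adjusted p = 0.599). The mast cell call was lost without control replicate 1 or 2 or TMA-ARB replicate 8 or 10 (adjusted p 0.0655 to 0.297). Dendritic cell markers had a median of -0.57 with 12 of 13 negative (camera adjusted p = 0.000924; adjusted p = 0.313 with an estimated correlation). Itgax was at -0.72 and Xcr1, a cross-presenting dendritic cell gene, at 1.06, and the medians were -0.51 below the 5% share, -0.53 above it and -0.40, still called lower, with the covariate. Erythroid markers, all 5 negative, had a median of -0.79 (camera adjusted p = 0.0137; adjusted p = 0.388 with an estimated correlation), with Alas2 at -1.54; without control replicate 2 the median was 0.05. The erythroid median was -1.39 below the 5% share and 0.14 above it, and with the covariate it was -0.46 and the call ended (adjusted p = 0.0726). The erythroid call was also lost without control replicate 2 or TMA-ARB replicate 6 or 10 (adjusted p 0.0503 to 0.324). Immediate early genes had 13 of 15 negative (median -0.37, camera adjusted p = 1.2e-05; adjusted p = 0.342 with an estimated correlation), with Fos at 36.7 ± 15.5 and 18.3 ± 7.22 CPM; the immediate early median was -0.22 without TMA-ARB replicate 7 and -0.75 without TMA-ARB replicate 8. The median was -1.12 below the 5% share and 0.18 above it, and -0.49, still called lower, with the covariate. In these lists 0 members passed over all genes and 0 adjusted over the list alone, with 2 macrophage, 0 mast cell, 1 dendritic, 0 erythroid and 3 immediate early members at an unadjusted p under 0.05.

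Cell cycle genes were positive in 23 of 26 cases with a median of 0.24 (camera adjusted p = 0.0291; adjusted p = 0.747 with an estimated correlation). Bub1 was at 0.38 ± 0.24 and Cenpe at 0.37 ± 0.26 (Bub1 0.14 without TMA-ARB replicate 7 and Cenpe 0.18 without TMA-ARB replicate 9; 0.0037 and 0.19 with sample weights). The list median was 0.12 without control replicate 2, 0.035 without TMA-ARB replicate 6, 0.11 without TMA-ARB replicate 7 and 0.40 without TMA-ARB replicate 8. The cell cycle median was 0.68 below a 5% mitochondrial share and -0.38 above it, so the direction differed between the sides. Cholesterol synthesis genes were positive in 17 of 18 cases (median 0.31, camera adjusted p = 0.000608; adjusted p = 0.388 with an estimated correlation), with Insig1 at 0.57 ± 0.24 and Sqle, the squalene epoxidase gene, at 0.33 ± 0.17; the median was 0.63 below the 5% share and -0.06 above it. Epithelial markers were positive in 6 of 7 cases (median 0.77, camera adjusted p = 0.0352; adjusted p = 0.344 with an estimated correlation). Krt8 measured 11.1 ± 3.86 CPM in controls and 25.9 ± 18.4 under TMA-ARB, and Krt19 3.16 ± 3.95 and 12.8 ± 21.9. TMA-ARB replicate 6 held 51.6 CPM of Krt19, and without it the log2 fold changes of Krt19 and Krt8 were 0.0058 and 0.71, and the epithelial and cholesterol medians 0.16 and 0.18. The epithelial median was 1.64 below the 5% share and 0.09 above it. With the log2 share as a covariate the cell cycle, cholesterol and epithelial medians were 0.32, 0.41 and 0.89, all 3 still called higher. The cell cycle call was lost without control replicate 2 or 4 or TMA-ARB replicate 6 or 7 (adjusted p 0.0540 to 0.995). The cholesterol call was lost without TMA-ARB replicate 6 (0.232), and the epithelial call without control replicate 1 or 5 or TMA-ARB replicate 6 or 8 (0.0636 to 0.515). Members passing numbered 0 over all genes and 0 adjusted over the list alone, with 0 cell cycle, 1 cholesterol and 1 epithelial gene at an unadjusted p under 0.05.

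**Figure D3:**
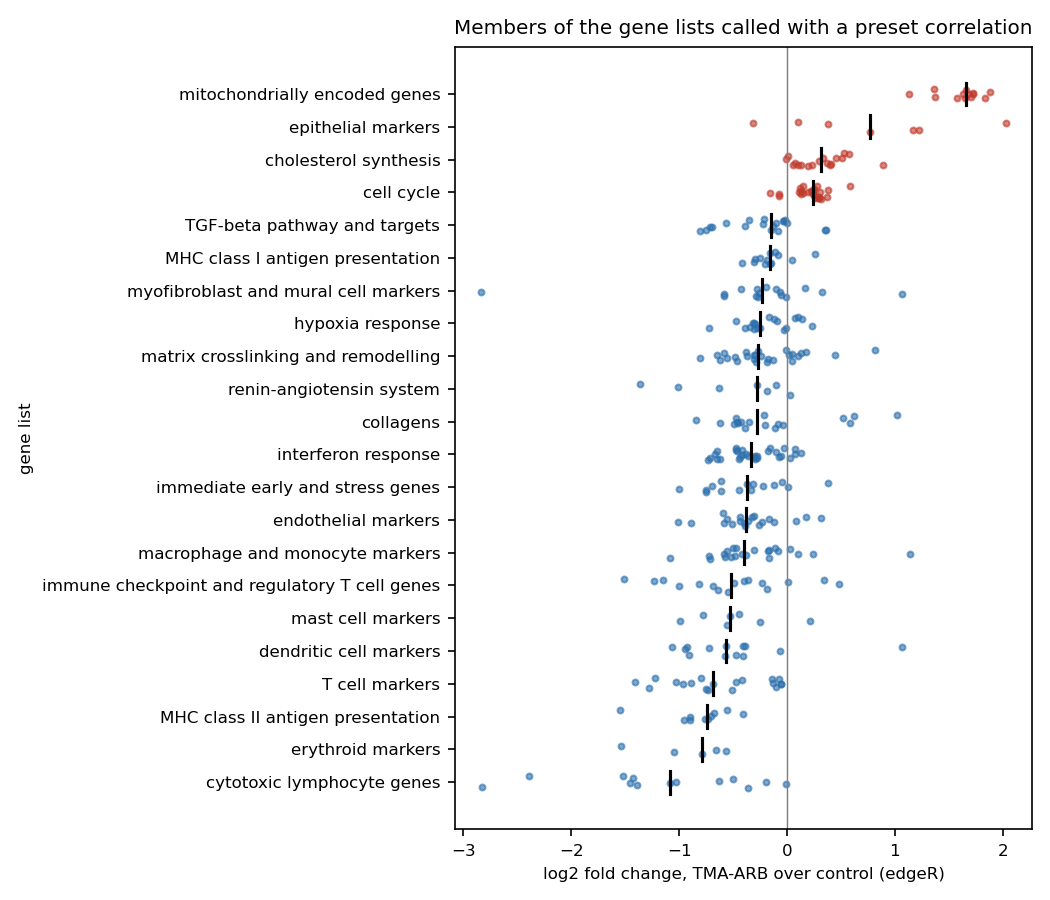
Log2 fold change (TMA-ARB over control, edgeR) of each measured member of the 22 lists called with a preset correlation, with red for lists called higher, blue for lists called lower and a black line at each median. The cytotoxic lymphocyte median lay at -1.09 and the mitochondrially encoded median at 1.66, and no member passed the adjusted threshold.

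The remaining 14 lists were not called. Camera adjusted p was 0.607 for matrix glycoproteins, 0.864 for inflammatory fibroblast markers, 0.423 for B and plasma cells, 0.126 for neutrophils, 0.633 for inflammatory cytokines and 0.411 for basal keratins. It was 0.651 for adipocyte, 0.453 for skeletal muscle and 0.994 for Schwann cell markers. For nuclear oxidative phosphorylation it was 0.239, for ribosomal proteins 0.166, for the unfolded protein response 0.994, for circadian output 0.994 and for glucocorticoid targets 0.104. Some passed camera in other settings. Skeletal muscle markers were called lower with no low-count filter (median -2.47) and with 1 library left out (-1.87 without control replicate 2 and -1.82 without control replicate 4). Glucocorticoid targets were called lower with the mitochondrial share as a covariate (-0.27), with a term for the 5% split (-0.29) and in libraries below it (-0.89). They were also called lower without TMA-ARB replicates 8, 9 and 10 (-0.61) and with 1 library left out (-0.37 without control replicate 5, -0.21 without TMA-ARB replicate 8, -0.25 without TMA-ARB replicate 9 and -0.26 without TMA-ARB replicate 10). Neutrophil markers were called lower with 1 library left out (-0.50 without control replicate 3, -0.56 without control replicate 5 and -0.69 without TMA-ARB replicate 7), and ribosomal proteins higher (0.090 without control replicate 4 and 0.18 without TMA-ARB replicate 6). Oxidative phosphorylation was called higher with 1 library left out (0.13 without control replicate 1 and 0.15 without TMA-ARB replicate 8), below the 5% share (0.25) and without those 3 TMA-ARB libraries (0.24). Circadian output was called lower without those 3 (-0.46). Matrix glycoproteins were called higher below the 5% share (0.084) and lower above it (-0.20). In none of these lists did a member pass over all genes (0) or adjusted over the list alone (0). The median and mean fold change differed in sign for matrix glycoproteins (-0.06 and 0.20), inflammatory fibroblast markers (-0.09 and 0.00), the unfolded protein response (-0.02 and 0.02) and circadian output (-0.02 and 0.05).

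**Figure D4:**
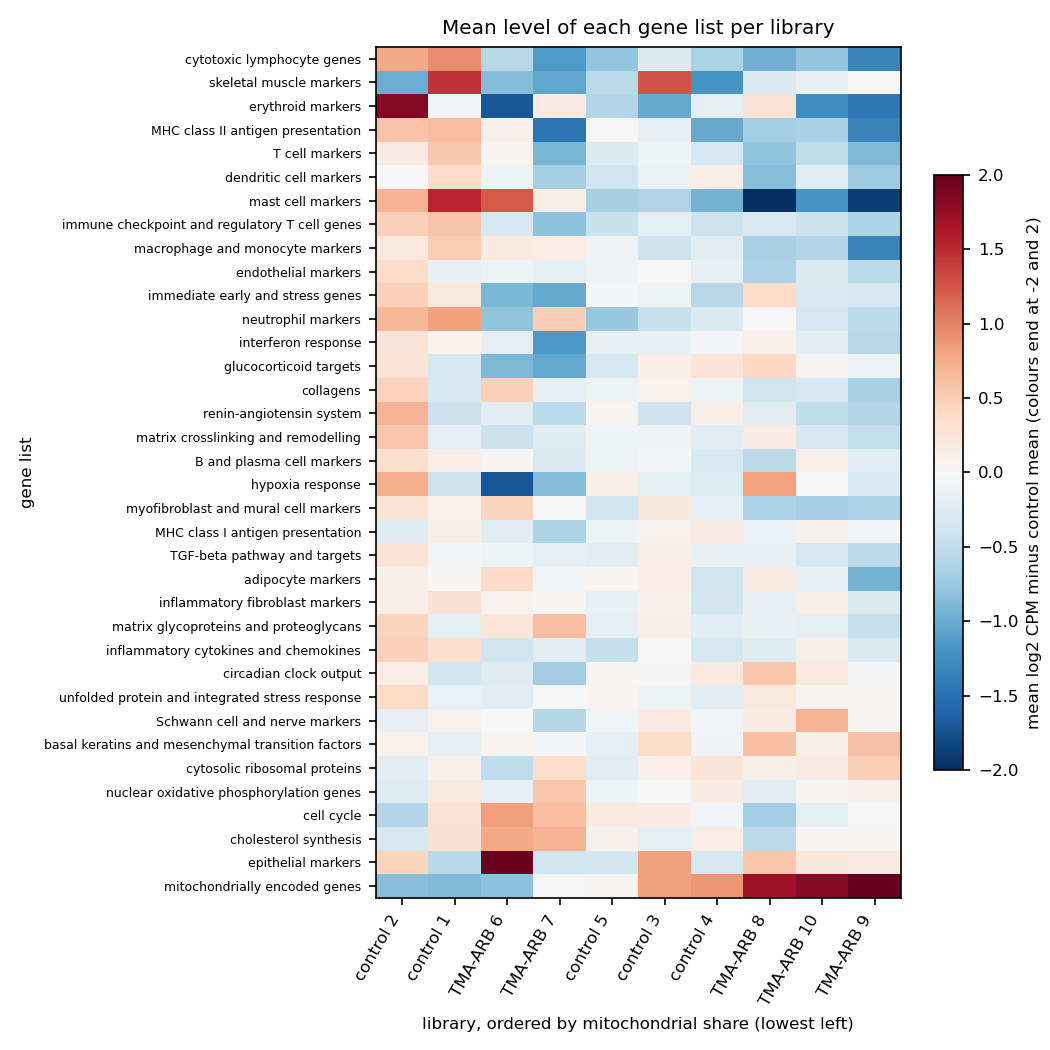
Mean log2 CPM of each tested list in each library minus the control mean, with libraries ordered from the lowest to the highest mitochondrial share; colours end at -2 and 2. The macrophage row fell along the order (r = -0.97), and the mitochondrially encoded row set the order.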

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

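The values here come from a comparison of each library with the other 4 of its group that was planned with the analysis; 0 tests in this part were chosen only after the result was seen. A library is listed when its gap to the nearest other, divided by the range of its 5 libraries, exceeded Dixon's 95% critical value of 0.71. Of 278 groups of values examined, 11 (3.96%) were listed, where chance lists about 1 in 20. Most named genes among them entered by a small unadjusted p in these same data, so that rate is only a rough guide. Gene levels were compared as log2 CPM and are given as CPM.

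TMA-ARB replicate 9, the library with a mitochondrial share of 25.0%, stood apart for Amd2 at 52.0 CPM (other TMA-ARB libraries 21.5 to 27.6) and for Msx1 at 4.82 CPM (others 2.17 to 2.54). TMA-ARB replicate 7 was low for Pdgfrb at 48.4 CPM (others 89.2 to 109) and for Nkg7 at 1.84 CPM (others 3.57 to 4.14). Control replicate 2 was high for Col6a2 at 429 CPM (other controls 181 to 211), for Plod1 at 205 CPM (others 109 to 130) and for Hba-a1 at 245 CPM (others 50.9 to 77.3), and low for Pcna at 170 CPM (others 249 to 289). It was also high for the mean of the crosslinking and remodelling list, 0.56 above the control mean on the log2 scale (others -0.23 to -0.07). Control replicate 4 was low for the adipocyte list at -0.39 (others 0.05 to 0.15), and control replicate 1 for the circadian list at -0.39 (others 0.02 to 0.19).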

How the results depend on the processing

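The settings that involve the mitochondrial share and the exact permutation of list means were chosen only after the results were seen. EdgeR called 0 genes in each direction with all libraries (457 at an unadjusted p under 0.05), and 0 under RLE scaling, no low-count filter, a mean of at least 5 CPM, both marker covariates, an adjusted p under 0.10 and each library left out in turn. With 1 library left out, 224 (without control replicate 2 or TMA-ARB replicate 9) to 1219 (without TMA-ARB replicate 6) genes reached an unadjusted p under 0.05. DESeq2 called 1 higher and 1 lower gene (826 at an unadjusted p under 0.05). Limma-voom with sample weights called 0 (1389). Libraries above a 5% mitochondrial share alone gave 1 gene higher (Pira2) and 3 lower (Aqp1, Rcn3 and Lrrc15), named after their values were seen. Pira2 averaged 0 CPM in those controls and 5.36 in those TMA-ARB libraries. With all libraries the log2 fold changes were Pira2 2.08, Aqp1 -1.43, Rcn3 -0.47 and Lrrc15 -0.29 (edgeR adjusted p = 0.997 each). The preset correlation called 4 lists higher and 18 lower. The counts were 4 and 18 with RLE scaling, 3 and 18 with no low-count filter, 3 and 15 with a mean of at least 5 CPM, 4 and 18 with the adipocyte covariate, 3 and 17 with the muscle covariate, 3 and 13 with the mitochondrial share as a covariate, 3 and 16 with a term for the 5% split and 3 and 18 with the mitochondrial genes left out, within 1.5 times of these, and edgeR called 0 genes in each. An estimated correlation, fry and the exact permutation of list means called 0 and 0 each, and the cause was not tested. With a smallest possible p of 0.00794, the exact permutation could not call 1 list alone after adjustment. Leaving out 1 library gave 2 (without TMA-ARB replicate 6) to 4 lists higher and 13 (without control replicate 2) to 20 (without control replicate 5) lower. Libraries below a 5% share gave 6 higher and 11 lower, those above 2 and 9, and leaving out the 3 TMA-ARB libraries above 10% gave 4 and 10; fewer libraries entered each. The difference in mitochondrial share stayed positive, from 2.69 points (without TMA-ARB replicate 9) to 8.38 (without TMA-ARB replicate 6, exact permutation p = 0.0397), against 0.143 with all libraries. That in the share of the 10 most abundant genes ran from 1.64 (without TMA-ARB replicate 9) to 6.25 points (without TMA-ARB replicate 6, exact permutation p = 0.0397), against 0.183 with all. Depth limits Agtr1a and Agtr1b, at 72 and 7 counts in all.

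The following values took the opposite sign to the value with all libraries and the main settings; the cause was not tested unless stated. They are log2 fold changes of genes or median log2 fold changes of lists. With sample weights, Tagln -0.13. With no low-count filter, adipocyte 0.38. With a mean of at least 5 CPM, cytokines 0.16, adipocyte 0.070 and Schwann -0.13. With the adipocyte covariate, matrix glycoproteins 0.047, basal keratins -0.019 and unfolded protein 0.017, and with the muscle covariate, circadian 0.041. With the mitochondrial share as a covariate, Hbb-bs 0.019, matrix glycoproteins 0.11, inflammatory fibroblast 0.16, cytokines 0.0012, basal keratins -0.15, ribosomal -0.0027 and unfolded protein 0.023. With a term for the 5% split, matrix glycoproteins 0.013, inflammatory fibroblast 0.073, cytokines 0.018 and basal keratins -0.046. In libraries below a 5% share, matrix glycoproteins 0.084, median log2 fold change of myofibroblast and mural cell markers 0.51, inflammatory fibroblast 0.17, median log2 fold change of macrophage and monocyte markers 0.041, basal keratins -0.054 and Schwann -0.40; matrix glycoproteins and myofibroblast passed camera in that direction. In libraries above it, Tagln -0.16, Pfkfb3 0.11, Ldha 0.061, Egln3 0.28, Trbc1 0.12, Ctla4 0.023, Cd14 0.072, Pcna -0.13, Krt19 -0.43, Hba-a1 0.14, Hbb-bs 0.57, median log2 fold change of matrix crosslinking and remodelling 0.026, inflammatory fibroblast 0.28, hypoxia 0.55, median log2 fold change of B and plasma cell markers 0.34, median log2 fold change of neutrophil markers 0.083, cytokines 0.22, median log2 fold change of cell cycle -0.38, adipocyte 0.45, erythroid 0.14, median log2 fold change of immediate early and stress genes 0.18, oxidative phosphorylation -0.13, median log2 fold change of cholesterol synthesis -0.065, unfolded protein 0.093 and circadian 0.16; hypoxia and cell cycle passed camera in that direction. Without the 3 TMA-ARB libraries above 10%, Tpsab1 0.21, Tpsb2 0.43, Krt18 -0.20, mt-Nd4l -0.44, mt-Nd4 -0.45, mt-Nd1 -0.37, matrix glycoproteins 0.11, myofibroblast 0.38, inflammatory fibroblast 0.00074, macrophage 0.22, mast cell 0.32, basal keratins -0.26, Schwann -0.45, median log2 fold change of mitochondrially encoded genes -0.60 and ribosomal -0.0020; the mitochondrially encoded list passed camera in that direction, and those libraries were left out for that measure. With 1 library left out, the ranges that crossed 0 were Hba-a1 -1.15 to 0.051, Hbb-bs -1.26 to 0.41, Tpsab1 -1.38 to 0.0046, median log2 fold change of adipocyte markers -0.27 to 0.036, median log2 fold change of basal keratins and mesenchymal transition factors -0.074 to 0.20, median log2 fold change of circadian clock output -0.15 to 0.18, median log2 fold change of cytosolic ribosomal proteins -0.027 to 0.18, median log2 fold change of erythroid markers -1.15 to 0.051, median log2 fold change of hypoxia response -0.57 to 0.055, median log2 fold change of inflammatory cytokines and chemokines -0.33 to 0.048, median log2 fold change of inflammatory fibroblast markers -0.14 to 0.20, median log2 fold change of mast cell markers -1.36 to 0.0046, median log2 fold change of matrix glycoproteins and proteoglycans -0.13 to 0.12, median log2 fold change of nuclear oxidative phosphorylation genes -0.082 to 0.15, median log2 fold change of Schwann cell and nerve markers -0.063 to 0.30 and median log2 fold change of unfolded protein and integrated stress response -0.059 to 0.036. By edgeR, 0 of 100 named genes passed the threshold in any fit with 1 library left out, and 3 changed sign.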

Other observations

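The tests that involve the mitochondrial share (correlations, also with group means removed, the covariate with its list mean differences, the removal from the host list correlations and the split at 5%) and the sequence match of Ccrn4l were chosen only after that share and the list calls were seen.

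Apart from treatment, the main axis of these tumours followed the mitochondrial share of their libraries, which ran from 2.07% to 25.0% without separate clusters. The first principal component correlated with its log2 value (Pearson r = 0.98, permutation p = 5e-05, adjusted p = 0.0001 over 2 measures; Spearman rho = 0.88, p = 0.00169, adjusted p = 0.00169; r = 0.95 without the 2 libraries farthest from the median). With no group in the model, edgeR called 1265 of 14047 nuclear genes higher and 1334 lower with the share at an adjusted p under 0.05, and 1129 and 1295 with the group in the model. Of 35 nuclear gene lists, 2 followed it after adjustment, both falling: macrophage markers (r = -0.97, permutation p = 3e-05, adjusted p = 0.00105; rho = -0.96, p = 3e-05) and mast cell markers (r = -0.90, permutation p = 0.00034, adjusted p = 0.00595; rho = -0.92, p = 0.00062). Myofibroblast markers (r = -0.80, permutation p = 0.0068; rho = -0.82, p = 0.00583; r = -0.69 without the 2 libraries) missed the threshold at an adjusted p of 0.0793 (0.0680 for rho). With each group's mean removed, r was 0.99 for the first component (exact permutation within groups p = 0.000625, adjusted p = 0.00118 over 2 measures) and -0.97 for macrophage markers (p = 0.000764, adjusted p = 0.0267 over 35 lists). Mast cell (r = -0.89, adjusted p = 0.0863) and myofibroblast markers (r = -0.77, adjusted p = 0.203) then missed the threshold, which 1 of the 35 lists passed.

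The real grouping and other groupings of the same libraries were compared for both kinds of call. For single genes the real count was 0, so all 100 splits examined of the 126 possible (the real split and 99 drawn) gave at least as many by construction, and the highest other gave 1; the comparison says nothing about chance. For lists with the preset correlation, 1 of the 100 splits, the real one, gave as many as its 22 lists; the highest other gave 19 and the median of the others was 11. The real count ranked first under this measure, but only 100 of the 126 possible splits were examined and arbitrary splits called a median of 11 lists. With an estimated correlation no split called any list (0), so the rank does not exclude chance. The split at a 5% mitochondrial share, fitted outside the 100, called 1617 genes and 6 lists. It parts the libraries as the sign of the first component does, so a large gene count along it says nothing further, and its 6 lists were fewer than the real 22.

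The lists lower under TMA-ARB were weighed against the mitochondrial share: with its log2 value in the model 12 of the 18 were still called lower. Medians were smaller in size for cytotoxic (-1.09 to -0.66), endothelial (-0.38 to -0.20), MHC class II (-0.74 to -0.48), T cell (-0.69 to -0.51) and dendritic cell genes (-0.57 to -0.40). They were larger for hypoxia (-0.25 to -0.67), MHC class I (-0.16 to -0.30) and immediate early genes (-0.37 to -0.49). They hardly moved for interferon (-0.34 to -0.33), crosslinking (-0.272 to -0.267), checkpoint (-0.52 to -0.50) and TGF-beta genes (-0.150 to -0.155). For the 6 lost calls the difference of list means (± SE) went from -0.41 ± 0.22 to -0.32 ± 0.25 for renin-angiotensin, -0.22 ± 0.23 to -0.0093 ± 0.20 for collagens, -0.29 ± 0.26 to -0.026 ± 0.20 for myofibroblast, -0.45 ± 0.33 to -0.019 ± 0.10 for macrophage, -0.79 ± 0.80 to 0.17 ± 0.42 for mast cell and -0.78 ± 0.64 to -0.52 ± 0.73 for erythroid genes; each moved toward or past 0, renin-angiotensin the least in size. The part that a straight line on the log2 share gives was above 0 for hypoxia (0.29), MHC class I (0.12), immediate early (0.098) and interferon genes (0.019), opposite to their differences, but its 95% interval included 0 for all 4. That interval lay below 0 for macrophage (-0.43, -0.52 to -0.33), mast cell (-0.96, -1.39 to -0.53), myofibroblast (-0.27, -0.46 to -0.067) and collagen genes (-0.21, -0.42 to -0.0057). For every other list it included 0. With the share in the model the difference that was left had a 95% interval below 0 for 0 of the 18 lists. Without the share, endothelial, T cell, cytotoxic and dendritic lists had an unadjusted exact permutation p under 0.05 (adjusted p = 0.381 each). The share took the endothelial difference from -0.35 ± 0.14 to -0.22 ± 0.12. It took T cell markers from -0.61 ± 0.24 to -0.41 ± 0.23 and dendritic markers from -0.51 ± 0.20 to -0.41 ± 0.21. For other lists the SE was wide without the share too (interferon -0.40 ± 0.22, hypoxia -0.42 ± 0.47). With the share those differences were no smaller in size (-0.42 ± 0.27 and -0.71 ± 0.49), while that of cytotoxic genes went from -0.95 ± 0.38 to -0.67 ± 0.38. For macrophage, mast cell, myofibroblast and collagen genes the line on the share took up most of the difference or more. The SEs of those differences were wide without the share too. For the other lists the intervals do not assign the differences to the share. For no list do they tell share and treatment apart. A smaller share of host cells in the treated tumours also stays open. Within groups, 9 host cell lists had a median pairwise correlation of 0.599 over 36 pairs (lowest 0.140), and 0.210 once the mitochondrial share was removed too. These lists thus varied together among tumours of a group, which cannot show whether treated tumours held fewer host cells. An effect of TMA-ARB stays open as well.

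The higher level of mitochondrially encoded genes in TMA-ARB libraries rested on replicates 8, 9 and 10. If more mitochondria per cell raised the nuclear oxidative phosphorylation genes too, the mean of that list would follow the log2 share. It did not (Pearson r = 0.0189, permutation p = 0.959, and Spearman rho = 0.14, permutation p = 0.708). Without the 2 libraries farthest from the median r was -0.09, and with group means removed it was -0.04 (exact permutation within groups p = 0.940). The missing correlation argues against that account only under this premise, which was not tested, and CPM does not measure mitochondria per cell. RNA quality, tissue necrosis and a treatment effect were not tested and stay open.

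Ccrn4l was picked after its values were seen because it followed the share, so its correlation describes the pattern and tests nothing (Pearson r = 0.93; Spearman rho = 0.88; r = 0.85 without the 2 libraries and 0.92 with group means removed). It ran from 930 CPM in control replicate 2 to 8587 CPM in TMA-ARB replicate 9. Reads shared with mitochondrial transcripts would need a long common stretch. The longest match of 4 annotated transcripts of this gene to 37 mitochondrial transcripts at 90% identity or more was 22 bases, under the 30 set before the search as too short. No biological explanation was tested.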
